A study of Mus musculus with 2 samples.

How the data were processed

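RNA sequencing libraries from cultured mouse oligodendrocyte lineage cells were compared, 1 library per genotype. Per the labels' protocols, precursor cells were immunopanned from the cortices of C57BL/6 pups aged 4 to 7 days, first on plates coated with anti-GalC and then on plates coated with anti-O4. They were expanded with PDGF-AA (20 ng/ml), CNTF (10 ng/ml), bFGF (20 ng/ml) and NT3 (1 ng/ml). Differentiation was started with triiodothyronine (T3, 60 nM) while PDGF-AA, bFGF and NT3 were withdrawn, and cells were taken on day 2. The control library is labelled wild type and the Seh1cKO library mutant; the Cre driver and the deleted exons are not given in the sources used here. The labels name no replicate, number of animals, sex or batch.

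For each library the authors deposited a gene table with an expected count and an FPKM value per gene, a read count scaled by transcript length and library size, under Entrez gene identifiers and symbols. The submitters' processing notes name HTSeq, StringTie and the mm10 build, and do not say which tool made which column; the aligner and the library strand setting are not given in the sources used here. The deposited expected counts were not whole for 29.3% of genes in the control library and 29.5% in the Seh1cKO library. Reads shared between genes or isoforms may have been split in the authors' counting, which was not tested. The expected counts summed to 20730124 and 20599573. Genes without reads are left out of each table, and such genes were set to 0 here. The deposited FPKM values were within 5% of the expected count divided by the deposited transcript length and the library total for 98.1% of the 8891 control genes at 5 FPKM or more, and for 98.2% of 9195 in the Seh1cKO library.

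A further table deposited by the authors lists genes for the Seh1cKO over control comparison with a log2 fold change, a p-value and a false discovery rate. The test behind these p-values is not given in the sources used here. In that table the authors' log2 fold change equals the log2 of the ratio of both deposited FPKM values for all 896 genes (tolerance 0.01), and a gene missing from a library carries an FPKM of 0.01. This replacement applied to 40 control values and 20 Seh1cKO values. Spreadsheet software had turned 26 gene symbols of the library tables into dates, so genes were matched by identifier; 18611 of 18651 identifiers matched the RefSeq gene table of GRCm38.p6, the assembly on which mm10 is based, and coordinates are taken from that table. None of the columns of per-sample values was left unmapped.

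Expected counts were rounded to whole numbers and scaled to a library total of 1000000 reads, a unit written CPM. The log2 ratio of a gene is log2(CPM + 1) in Seh1cKO minus log2(CPM + 1) in control, which understates the difference of low genes. Genes with a mean of at least 1 CPM over both libraries were measured (13758 genes), and a threshold of 2-fold was applied on that scale. Folds of single genes are ratios of CPM without the pseudocount, with an exact 95% Clopper-Pearson interval from the 2 counts. With 1 library per group no test across conditions was possible, and these intervals cover counting error only, not variation between cultures or animals. Reads carry no molecular identifiers here, so the intervals may be too narrow even for counting. A count of 0 allows up to 3 counts, which is 0.145 CPM in the control and 0.146 CPM in the Seh1cKO library.

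Before the data were examined, 29 gene lists (461 genes) were fixed: oligodendrocyte stages, lineage transcription factors, inhibitors of differentiation, cholesterol synthesis, cell cycle, nucleoporins, the GATOR and SWI/SNF complexes, stress and signalling responses, markers of other cell types, sex-linked genes and quality lists. For each list with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean CPM in 20 bins. The percentile describes these libraries and is no p-value. The 95% interval of a median is the binomial order-statistic interval over list members. The mitochondrially encoded list matched no symbol and was not analysed here, and no erythroid globin gene reached 1 CPM. Named genes followed a rule set at the same time: Seh1l, Olig2, Brd7, Olig1, Sox10 and Myrf; the 10 genes of each direction with the largest log2 ratio at a mean of at least 5 CPM, leaving out unnamed gene models, pseudogenes, ribosomal, globin, mitochondrial and sex genes; up to 4 members of each main list and 2 of each side list by absolute log2 ratio; the 3 most abundant members of each cell type or quality list; and the first 5 of each direction in the authors' table. Not every gene that the rule picks is printed. The Seh1l, Sec13, Smarca4, Tcf7l2, Nkx6-2, Egr1, Gpr17 and Bmp4 genes each stand in 2 lists.

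The fixed alternatives were pseudocounts of 0.1 and 5, rescaling by the median of ratios or the upper quartile, the deposited FPKM values, no floor or a floor of 5 CPM, thresholds of 1.5-fold and 4-fold, random lists without matching, and stricter rows of the authors' table. The calculations were tested on simulated counts for the 13758 genes of the Seh1cKO against control comparison, with 200 genes changed. Of the genes set 3-fold apart, 91.0% passed the 2-fold threshold at 1 CPM or more and 100% at 5 CPM or more; for genes set 6-fold apart the shares were 99.0% and 100%. No unchanged gene passed, 95.8% of 1000 counting intervals held the set ratio, and 2 of 40 unshifted lists fell outside the 2.5 to 97.5 percentiles. The simulated counts held Poisson counting error only, with no variation between cultures or animals and no genes that move together. These shares therefore do not say how often real calls or percentiles would arise without an effect of genotype. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.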

Results

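Gene expression was measured by RNA sequencing in immature mouse oligodendrocytes 2 days after the start of T3-driven differentiation, in 1 control culture and 1 culture from mice with a conditional knockout of Seh1l (Seh1cKO). Seh1l encodes Seh1, a protein of the Y-shaped scaffold of the nuclear pore and of the GATOR complexes that signal amino acid supply. The series asks how Seh1, with Olig2 and Brd7, acts in oligodendrocyte differentiation and myelination. The libraries were of near equal depth, at 20730124 assigned reads in control and 20599573 in Seh1cKO. They listed 17655 and 18027 genes, of which 17031 were in both. There was no replicate in either group, so each difference is one between 2 libraries. Intervals of single genes are exact 95% intervals for counting error. Those of list medians are 95% order-statistic intervals over list members and hold no counting error. No test of the genotype was possible.

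Seh1l itself (Entrez 72124, GRCm38 chromosome 18, 67774876 to 67795487) was present at 32.1 CPM (reads per 1000000 reads of the library) in control and 18.5 CPM in Seh1cKO. That is 1.73-fold lower (1.53 to 1.97), from 666 and 382 reads, so 0.577 of the control level (0.508 to 0.656) remained in the library labelled Seh1cKO. Reads were counted over the whole gene, and reads from exons outside the deleted part, if any, are included. The Seh1cKO library also held markers of other cells, given below, and which cells carried the remaining Seh1l reads is not known from bulk RNA. The other partners named in the series title differed less. Olig2, the basic helix-loop-helix factor of the lineage, was at 496 CPM in control and 648 CPM in Seh1cKO, 1.31-fold higher (1.27 to 1.34). Brd7, a bromodomain subunit of the PBAF chromatin remodeller, was at 76.8 and 71.8 CPM, a ratio of 0.934 whose interval of 0.870 to 1.00 was not separated from equality at this depth. Olig1 was at 864 and 873 CPM, a ratio of 1.01 (0.989 to 1.03).

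Across the transcriptome, most genes stood close together. Of the 13758 genes measured, 13186 (95.8%) were within 2-fold, 394 were at least 2-fold higher and 178 at least 2-fold lower in Seh1cKO. The median log2 ratio of all genes was 0.07. Of the 394 higher genes, 166 were at a mean of 1 to 5 CPM, against 32 of the 178 lower genes. On the deposited FPKM scale the counts were 228 higher and 173 lower, which moved the share of higher genes from 68.9% to 56.9%. Without a replicate, neither count separates the genotype from culture-to-culture variation.

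Genes of myelin and of mature oligodendrocytes were mostly lower in Seh1cKO. Mag, a myelin adhesion protein of the inner myelin membrane (chromosome 7, 30899175 to 30914922), was at 144 CPM in control and 8.74 CPM in Seh1cKO, 16.5-fold lower (14.2 to 19.2). Mbp, which compacts the myelin sheath (chromosome 18, 82475091 to 82585637), was 9.86-fold lower (9.30 to 10.5). Nkx6-2, a homeodomain factor of maturing oligodendrocytes, was 5.36-fold lower (4.64 to 6.2). Of the 22 measured members of this list, 12 were at least 2-fold lower, 7 were within 2-fold and 3 were at least 2-fold higher. The 3 higher members, named after their values were seen, were Trf (transferrin), Mal and Apod (apolipoprotein D), of which Trf and Apod are secreted and carry iron and lipids. The list median log2 ratio was -1.41 (interval -2.27 to 0.56 over members), below the medians of all 10000 matched random lists. The median reached -0.14 when members under 1 CPM were kept, because 8 late myelin genes were hardly expressed in either library. The libraries also differed in sex-linked genes and in fibroblast markers, as given with the markers of other cells.

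Genes of the premyelinating stage were lower as well. Tmem163, a zinc transporter, was at 69.6 CPM in control and 6.51 CPM in Seh1cKO, 10.7-fold lower (8.96 to 12.9). Kif19a, a kinesin, was 6.48-fold lower (5.44 to 7.75), and Enpp6, a choline phosphodiesterase that marks newly forming oligodendrocytes, 6.75-fold lower (5.48 to 8.40). The long non-coding RNA 9630013A20Rik was 6.39-fold lower (4.78 to 8.71). Of 19 measured members, 12 were at least 2-fold lower and none at least 2-fold higher. The median log2 ratio of -1.28 (-2.15 to -0.91) lay below those of all matched random lists. The same 2 libraries differed in sex-linked genes and in fibroblast and mural cell markers (median 1.25).

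Precursor genes did not share this direction as a group. Pdgfra, the PDGF receptor that marks precursor cells and is also expressed by fibroblasts, whose markers were higher in the same library (median 1.25), was at 156 CPM in control and 277 CPM in Seh1cKO, 1.77-fold higher (1.70 to 1.85), and the proteoglycan enzyme Xylt1 was 2.99-fold higher (2.28 to 3.96). C1ql1 was 2.64-fold lower (2.36 to 2.96) and the matrilin Matn4 1.56-fold lower (1.49 to 1.64). Of 20 members, 1 was at least 2-fold higher, 1 at least 2-fold lower and 18 within 2-fold. The median log2 ratio of 0.26 (-0.03 to 0.57) was at the 99.98 percentile of matched random lists.

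**Figure D1:**
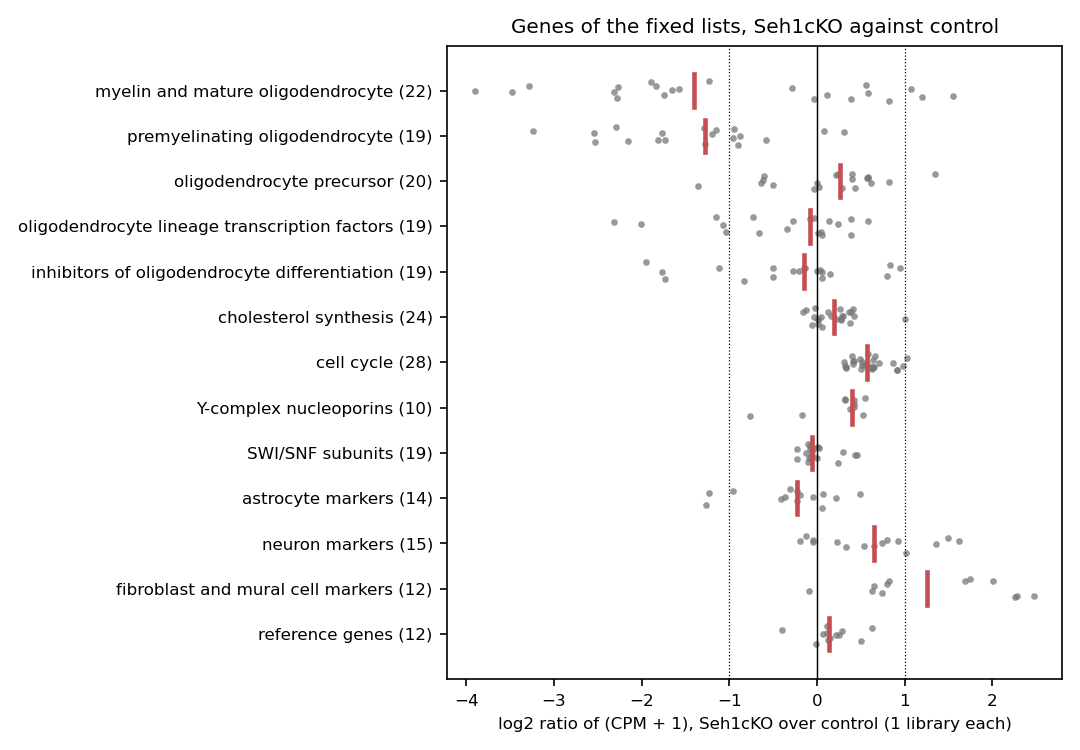
Log2 ratio of (CPM + 1), Seh1cKO over control, for measured members of 13 gene lists (number of members in brackets), with 1 library per genotype. Grey points are genes, red bars are list medians, the solid line marks equality and the dotted lines 2-fold. The myelin and premyelinating medians lie at -1.41 and -1.28, the cell cycle list lies wholly to the right of equality, and the fibroblast and mural cell list has a median of 1.25.

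Lineage transcription factors were split. Myrf, the activator of myelin genes (chromosome 19, 10208271 to 10240777), was at 188 CPM in control and 45.9 CPM in Seh1cKO, 4.09-fold lower (3.80 to 4.39). Sox10 was 2.05-fold lower (1.98 to 2.13), Nkx2-2 2.11-fold lower (1.97 to 2.27) and Tcf7l2, the Wnt effector factor of newly differentiating cells, 2.25-fold lower (2.06 to 2.47). With Nkx6-2, 5 of 19 measured factors were at least 2-fold lower and 14, with Olig1 and Olig2, were within 2-fold. The list median was -0.08 (-1.03 to 0.14), at the 4.13 percentile of matched random lists. The percentile was 2.30 among lists without matching, and 0.08 with a median of -0.18 without genes on chromosomes X and Y. Known inhibitors of differentiation were lower in 11 of 19 cases. Hes5, a Notch effector, was 4.02-fold lower (3.57 to 4.54), the receptor Gpr17 3.42-fold lower (3.26 to 3.58), Bmp4 3.47-fold lower (3.08 to 3.92) and Id3 2.17-fold lower (2.10 to 2.24). Those 4 were the members at least 2-fold lower, and the other 15 of 19 were within 2-fold, with a list median of -0.14 (-0.83 to 0.06) at the 0.21 percentile of matched random lists. Gpr17 and Bmp4 also belong to the premyelinating list. Astrocyte markers were lower in the same library (median -0.23) and fibroblast and mural cell markers higher (median 1.25). Which cells carried these reads is not known from bulk RNA.

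All 28 measured cell cycle genes were higher in Seh1cKO, with log2 ratios from 0.31 to 1.03 and a median of 0.58 (0.50 to 0.64), a 1.49-fold difference. Fibroblast and mural cell markers were higher in the same library (median 1.25), and which cells carried the cell cycle reads is not known from bulk RNA. Mcm5, a subunit of the replicative helicase, was 2.08-fold higher (1.88 to 2.30), and Mcm3 and Mcm6 were both 1.91-fold higher. Rrm2, which makes deoxynucleotides for DNA synthesis, was 1.98-fold higher (1.86 to 2.11). One of these genes, Mcm5, passed 2-fold. Ccnd1, the cyclin of G1 and a member of the Wnt target list, was at 495 CPM in control and 1348 CPM in Seh1cKO, 2.72-fold higher (2.66 to 2.79). It was the 1 gene of 11 in that list past 2-fold once the pseudocount was added. Lef1 was 2.49-fold higher (1.48 to 4.36) without it, at 1.01 and 2.52 CPM, and the list median was 0.21 (-0.28 to 0.81).

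Most components of the nuclear pore were slightly higher, in libraries that also differed in fibroblast markers and sex-linked genes. In the Y-complex, 8 of 10 genes were higher and 2, Seh1l among them, lower, with Nup85 1.47-fold higher (1.34 to 1.61), Nup160 1.47-fold higher (1.26 to 1.72) and Nup98 1.35-fold higher (1.22 to 1.49); none passed 2-fold. The median log2 ratio was 0.40 (-0.18 to 0.52). Among 20 other nucleoporins 19 were higher, with a median of 0.29 (0.19 to 0.37), and Pom121 (1.46-fold, 1.36 to 1.58) and Nup153 (1.43-fold, 1.31 to 1.56) stood furthest. The 8 GATOR genes were all within 2-fold with a median of 0.03, which turned negative (-0.04) after rescaling by the median of ratios. Wdr59 was 1.15-fold lower (1.02 to 1.30). All 19 SWI/SNF subunits were within 2-fold, with a median of -0.05 (-0.10 to 0.02). Smarca2 was 1.38-fold higher (1.30 to 1.46) and Actl6b, at 3.47 and 5.05 CPM, 1.45-fold higher (1.07 to 1.99).

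Of 24 genes of cholesterol synthesis, which supplies the lipid of myelin membranes, 19 were higher and 5 lower. All but 1 were within 2-fold, and the sterol transporter Stard4 was 2.07-fold higher (1.82 to 2.37). Idi1 was 1.34-fold higher (1.29 to 1.40) and Sc5d 1.33-fold higher (1.23 to 1.45), with a list median of 0.19 (0.01 to 0.30). That median was at the 99.97 percentile of matched random lists and at 95.8 among lists without matching. These reads, too, come from libraries that differ in fibroblast and mural cell markers (median 1.25).

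Stress and signalling genes were measured in the same 2 libraries, in which fibroblast and mural cell markers were higher in Seh1cKO (median 1.25). All 17 p53 target genes were higher, with a median of 0.44 (0.27 to 0.58); Perp, a desmosomal gene of epithelia, was 3.15-fold higher (2.49 to 4.01) and Plk2 1.83-fold higher (1.68 to 2.00). Of 18 genes of the ATF4 and amino acid response, 14 were lower, with a median of -0.31 (-0.40 to -0.01), Trib3 at 1.56-fold lower (1.35 to 1.82) and Ddit4 at 1.46-fold lower (1.38 to 1.54). In the hypoxia and glycolysis list 12 of 14 genes were lower, with a median of -0.44 (-0.76 to -0.04). Pdk1, which diverts pyruvate from the mitochondria, was 2.42-fold lower (2.22 to 2.64) and Bnip3 2.18-fold lower (2.05 to 2.32). Immediate early genes had a median of 0.46 (0.18 to 0.76), with the AP-1 gene Fosl1 5.63-fold higher (4.18 to 7.72) and Egr1 1.78-fold higher (1.58 to 2.00). Of 9 measured cytokine genes 4 were at least 2-fold higher, among them Cxcl1 at 2.22-fold (2.08 to 2.37) and Ccl7 at 2.29-fold (1.92 to 2.74), with a median of 0.37 (-0.02 to 1.11) that was 1.06 with a floor of 5 CPM. The 11 interferon response genes were all within 2-fold, with a median of 0.19 (-0.02 to 0.44). Irf7 (1.40 and 2.28 CPM) and Isg15 (1.79 and 2.77 CPM) were near the floor. The thyroid hormone response genes went both ways, with Dio2, which activates thyroid hormone, 2.18-fold higher (2.04 to 2.33) and the corepressor Hr 1.58-fold lower (1.48 to 1.69); the median of -0.06 (-0.66 to 1.11) turned positive (0.012) on the deposited FPKM scale and with no floor or a floor of 5 CPM.

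Markers of other cells were found in both libraries and differed between them. Gfap, the intermediate filament of astrocytes, was the 4th most abundant gene in control at 5200 CPM and the 18th in Seh1cKO at 2214 CPM, 2.35-fold lower (2.32 to 2.37). The sodium pump subunit Atp1b2 was at 2873 and 2228 CPM, and the glutamate transporter Slc1a3 at 1227 and 1072 CPM. Of 14 astrocyte genes 2 were at least 2-fold lower and 12 within 2-fold, with a median of -0.23 (-0.96 to 0.06). Fibroblast and mural cell genes were higher in Seh1cKO in 11 of 12 cases. The collagen gene Col1a1 was at 45.2 CPM in control and 184 CPM in Seh1cKO, 4.08-fold higher (3.80 to 4.39), Col3a1 4.93-fold higher (4.47 to 5.44) and Tagln 1.68-fold higher (1.56 to 1.81). That list had a median of 1.25 (0.65 to 2.25), above all matched random lists, with 6 genes at least 2-fold higher. Neuron markers had a median of 0.66 (-0.04 to 1.01), which was 0.33 with a floor of 5 CPM, and the most abundant were near equality, with Map2 at 279 and 270 CPM and Tubb3 at 91.0 and 79.6 CPM; Stmn2 was 2.05-fold higher (1.86 to 2.27). Among 6 endothelial genes, Cdh5 was 13.6-fold higher (8.73 to 22.3), Slco1c1 2.01-fold higher (1.76 to 2.30) and Kdr at 5.35 and 4.95 CPM, with a median of 0.71 (-0.09 to 2.88). Microglia genes were low, with Cd68 at 3.67 and 8.30 CPM, Tmem119 at 0.868 and 4.17 CPM, and a median of 0.30 (-0.05 to 1.47) over 7 genes. Ribosomal protein genes and reference genes had medians of 0.15 and 0.14, with Rps2 at 1595 and 1776 CPM, Actb at 2816 and 2959 CPM, Gapdh at 3393 and 2575 CPM, and Eef1a1 at 6048 and 7392 CPM.

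Sex-linked genes stood on opposite sides. Xist, the RNA of the inactive X chromosome in females, was at 0.868 CPM in control and 341 CPM in Seh1cKO, 393-fold higher (248 to 663). The Y-linked gene Eif2s3y had 1705 reads in control and 1 read in Seh1cKO, and Ddx3y 1053 and 3 reads. The 5 sex-linked genes had a median log2 ratio of -3.97, 1 being higher and the 4 Y-linked genes lower. Genotype and sex-linked expression therefore cannot be separated in these 2 libraries. Without genes on chromosomes X and Y, an alternative chosen after seeing the data, the counts were 388 higher and 169 lower, and the myelin median was -1.23.

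**Figure D2:**
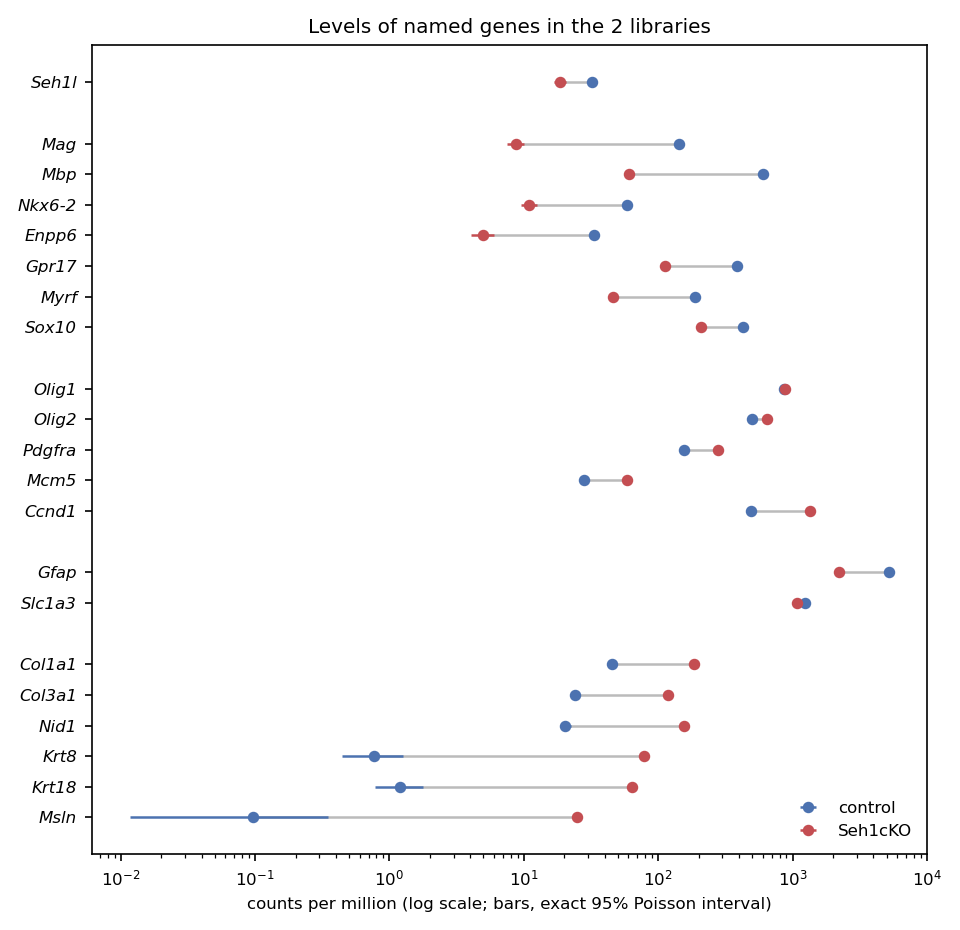
Levels in CPM of named genes in the control library (blue) and the Seh1cKO library (red) on a log axis; bars are exact 95% Poisson intervals and cover counting error only, with 1 library per genotype. Myelin genes such as Mag (144 and 8.74 CPM) are lower in Seh1cKO, Olig1 coincides, and Krt8, Krt18 and Msln are near or below 1 CPM in control and at 78.7, 63.9 and 24.9 CPM in Seh1cKO.

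With sex genes left out, Krt8 had the largest positive log2 ratio among genes at a mean of 5 CPM or more. Krt8, a keratin of simple epithelia (chromosome 15, 101996711 to 102004342), was at 0.772 CPM in control and 78.7 CPM in Seh1cKO, 102-fold higher (62.6 to 179), and its filament partner Krt18 was 53-fold higher (35.8 to 82.2). Msln, mesothelin, had 2 reads in control and 513 in Seh1cKO, a ratio of 258 (71.1 to 2137). Ly6a was 35.8-fold higher (21 to 67.7), Krt17 22.3-fold (13.3 to 40.4), Krt7 29.8-fold (14.2 to 74.9) and Cdh1, the epithelial cadherin, 36.9-fold (16.7 to 102). Thbd was 11-fold higher (8.37 to 14.8), the cytokine Il11 8.63-fold (7.26 to 10.3) and Anxa1 8.07-fold (6.98 to 9.35). Epcam, a further epithelial gene named after its value was seen, was at 7.91 and 7.04 CPM. Among the largest lower values, besides the myelin and premyelinating genes, were Tubb4a, a tubulin of oligodendrocytes, at 5.42-fold lower (5.20 to 5.64), the semaphorin receptor Plxnb3 at 5.25-fold (4.69 to 5.89) and its X-linked neighbour Srpk3 at 6.67-fold (4.99 to 9.08). H2-L, a class I histocompatibility gene, had 282 reads in control and 0 in Seh1cKO. That is at least 93.4-fold lower against the floor of 3 reads, with an exact lower bound of 75.5. Its identifier had no match in the RefSeq gene table of GRCm38.p6. Such genes share reads with near-identical copies and differ between mouse strains, so its value is uncertain. The labels give the strain C57BL/6 for both libraries, and whether their genetic background differed was not tested.

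The authors' deposited table lists 896 genes for this comparison, 659 higher and 237 lower in Seh1cKO. Its smallest absolute log2 fold change is 1.00 and its largest false discovery rate 9.61e-04, and these values come from 1 library per group. All 896 genes had the same direction in the library tables (100%). This was fixed nearly in full, because the fold changes are computed from the same FPKM values. All 572 genes past 2-fold here are in the authors' deposited table. That too was largely fixed, since the table rests on the same reads and the pseudocount used here shrinks ratios. Of the table's genes, 87 had a mean under 1 CPM, 73 of them listed as higher. Among the first by false discovery rate in the authors' deposited table were Xist, Krt8, Krt18, Nid1 and Spp1 among higher genes and Eif2s3y, Ddx3y, Mag and Mbp among lower genes. Nid1, a basement membrane protein, was 7.65-fold higher (6.91 to 8.48) in the counts, and Spp1, osteopontin, 6.50-fold higher (5.95 to 7.11). From the fixed lists, the authors' deposited table holds 12 lower and 3 higher myelin genes, 12 lower premyelinating genes and 5 lower lineage factors, and no nucleoporin, SWI/SNF or GATOR gene. Brd7, Olig1, Olig2 and Seh1l are not in it.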

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

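No paired analysis was possible because each group has 1 library. The alternatives without genes on chromosomes X and Y, and with only the genes of the authors' table (394 higher and 178 lower genes, as in the report), were chosen after seeing the data. The count of genes at least 2-fold higher (394) was 637 with a pseudocount of 0.1, 141 with a pseudocount of 5 and 228 with a floor of 5 CPM, so it depended on how low values were treated. It was 228 on the deposited FPKM scale as well, where the pseudocount and the floor were 1 FPKM and so not the same limits. How much of the drop they account for was not tested. The lower count (178) was 116 with a pseudocount of 5. With thresholds of 1.5-fold and 4-fold, 1297 and 63 genes were higher and 484 and 39 lower. At an absolute fold of 4 the authors' deposited table keeps 218 higher and 71 lower genes. Its folds are FPKM ratios without the pseudocount and the floor of 1 CPM, so these counts are not on the same scale. Seh1l stayed lower under every alternative run, with log2 ratios from -0.83 to -0.65. Of 212 list medians under alternatives, 208 stayed within the interval of the median over members, and no median turned sign except those of the GATOR and thyroid hormone lists. For wide intervals this is a weak criterion: the myelin median (-1.41) was -0.14 with no floor, -0.85 with a pseudocount of 5 and -1.23 with a floor of 5 CPM, all inside its interval of -2.27 to 0.56. The cytokine median (0.37) was likewise 1.06 with a floor of 5 CPM and 0.23 with a pseudocount of 5, the neuron median (0.66) 0.33 and 0.38, and the fibroblast and mural median (1.25) ranged from 0.82 to 1.72 over the alternatives. The 4 medians outside their interval were the SWI/SNF list (-0.13), the ribosomal protein list (0.075) and the reference genes (0.068) after rescaling by the median of ratios, and the sex-linked genes (-6.74) with a pseudocount of 0.1. Such rescaling shifts all genes by 0.07 on the log2 scale. Of 212 percentiles under alternatives 208 stayed on the same side of the limits that enclose the central 95 percent of random lists; lineage factors passed the lower limit without matching (2.30) and without genes on chromosomes X and Y (0.08), while cholesterol synthesis (95.8) and ribosomal proteins (90.9) left the upper one without matching. With 7 of 27 lists below and 12 above those limits, a percentile outside them is not rare here. The library tables hold 1 row per gene, so the alternative of the most abundant transcript was not run. Depth limits genes under 1 CPM, where the late myelin genes Mobp, Ermn and Aspa had 6 or fewer reads in each library.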

Other observations

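The 8 gene lists in this part, and the tests of lineage cells, scaling, sex, meningeal cells, epithelial cells and pooled animals, were chosen after the results they concern had been seen; the tests of choroid plexus cells and of X genes that escape inactivation were set before their values. The scaling and epithelial tests each replaced an earlier one, a rescaled myelin median (-1.48, -2.32 to 0.49) that could not decide and a list median (2.75) that held the very genes behind the question. Of 30 basement membrane and matrix genes 29 were higher in Seh1cKO and 18 at least 2-fold, with a median log2 ratio of 1.26 (0.65 to 1.67). Nid1 was 7.65-fold higher, and the abundant Fn1 (114 and 348 CPM), Col4a1 (145 and 394 CPM) and Tnc (97.6 and 278 CPM) were higher too. Timp1 was the lower member, at 222 and 181 CPM. Retinoid genes had a median of 0.86 (0.26 to 1.5), with Aldh1a2, which makes retinoic acid, at 3.18 and 29.2 CPM and Lrat at 17.8 and 5.73 CPM. This list shares Aldh1a2 with the mesothelium list and 1 gene with the leptomeningeal list, both given below, so it is not a fully separate observation. Of 12 tubulin genes, Tubb4a was at 742 and 137 CPM and Tuba1c at 20.5 and 110 CPM, while the other 10 were within 2-fold.

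The lower myelin list (median -1.41) was set against technical explanations. A culture with fewer oligodendrocyte lineage cells of every stage would lower precursor genes alike, and their median was 0.26 (-0.03 to 0.57). That argues against it as the whole cause only as far as these reads came from lineage cells. Pdgfra is also expressed by fibroblasts, whose markers were higher (median 1.25). Among lineage factors, Sox10 was 2.05-fold lower, while Olig1 was at a ratio of 1.01 and Olig2 1.31-fold higher. A smaller loss of lineage cells is not excluded. Scaling of the libraries would lower all genes alike, and the median of all measured genes was 0.068 (0.063 to 0.073). A value near 0 was largely fixed in advance, because both libraries were scaled to the same total, so it is no test of scaling. The myelin median was -1.48 after rescaling by the median of ratios. A different sex of the animals behind the 2 libraries stays open, because 0 pairs of control and Seh1cKO libraries had sex-linked reads of the same kind. Loss of Seh1l, the difference the design names, also stays open as untested, as does any difference between single cultures in the share of cells that had left the precursor stage.

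Keratin and claudin genes near 0 in control and clear in Seh1cKO, and higher matrix genes, may reflect other cells in that culture. Epithelial cells stay open. The 10 epithelial genes outside those that raised the question (Krt5, Krt14, Krt19, Grhl2, Elf3, Ovol1, Prss8, Dsp, Pkp3 and Esrp2) had 86 reads in control and 402 in Seh1cKO, a ratio of 4.70 (3.72 to 6.01), and 2.93 (2.25 to 3.84) without Krt19, but their values were known when they were picked, so the ratio could not have spoken against such cells. Epcam, which such cells would be expected to bring, was at 7.91 and 7.04 CPM, a ratio of 0.890 (0.707 to 1.12). The epithelial list had a median of 2.75 (1.28 to 3.18) over 15 genes. Meningeal cells could not be decided. Of 18 leptomeningeal genes 15 were higher, 8 of them at least 2-fold, and 0 were at least 2-fold lower. The list median of 0.97 (0.51 to 1.75) lay above all matched random lists, but its interval spans a 2-fold difference. In addition, 5 list genes were known from the fibroblast list. Of its abundant genes Col1a1 was 4.08-fold higher, while Igf2, the lowest member, was at 81.3 and 51.0 CPM. Choroid plexus cells were not decided either, with Ttr, the most abundant transcript of that tissue, 2.00-fold higher (1.76 to 2.28) at 17.6 and 35.2 CPM, and a list median without Krt8 and Krt18 of 0.47 (-1.07 to 0.96) over 5 genes, under the value of 1 set for such cells beforehand; with both keratins the median was 0.81. Expression of these genes by the Seh1cKO glia themselves was not tested. Positive panning on anti-O4 would be expected to remove most such cells. The astrocyte gene Gfap was at 5200 CPM in control and 2214 CPM in Seh1cKO, and whether its reads came from cells that escaped panning was not tested. How well panning removed other cells is not known here, so it does not decide the question, and bulk libraries do not show which cells carried the reads.

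Sex-linked genes fit male animals behind the control and female animals behind the Seh1cKO library: 8 X genes that escape inactivation had a median of 0.49 (0.11 to 0.76), against 0.07 for genes outside X and Y. Animals of both sexes pooled in each library are argued against, since the 4 Y-linked genes gave 3299 reads in control and 5 in Seh1cKO, 0.153% of the control level (0.049% to 0.356%). The 463 measured X genes as a whole had a median of 0.09 (0.05 to 0.12). The effect of sex on autosomal genes cannot be told apart from that of genotype here.

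Some further values stand out. The mesothelium list had a median of 2.85 (0.04 to 4.88) over 9 genes, 7 of them at least 2-fold higher; without its 4 keratins, shared with the epithelial list, the median was 2.10 (0.025 to 4.56) over 5 genes, and Upk3b and Wt1 had under 3 reads in each library. Cdh5 was at 1.01 and 13.8 CPM although the endothelial genes Cldn5, Tek and Emcn had at most 4 reads in either library. Esam, a further endothelial gene, was at 0.42 FPKM in control and 2.48 FPKM in Seh1cKO. Of the 6 measured endothelial genes, 2 were at least 2-fold higher and 4 within 2-fold. Cldn3 and Cldn4 had 0 reads in control and 154 and 186 in Seh1cKO, at least 51.7-fold and 62.4-fold higher against the floor of 3 reads, with exact lower bounds of 41.5 and 50.2.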
